A study of Drosophila melanogaster with 46 samples.

How the data were processed

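The series held 46 samples of Drosophila melanogaster in 19 groups: 28 ChIP-seq or input samples, 8 Hi-C samples and 10 RNA-seq samples. Eye discs came from wandering larvae, and the other samples from embryos. The files used here were 6 peak lists, for PSC and Su(z)12 in eye discs (2 replicates each, 500 discs per replicate), and 2 fold change tables, for a Pc mutant (2 replicates, 150 discs each) and for RNA interference against ph (4 replicates, with 4 replicates of RNA interference against white). The Hi-C samples and the histone mark, input and embryo ChIP-seq samples were not analysed here.

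Per the submitters' processing notes, the genome build was dm6 and the tools named were Bowtie2, SAMtools, MACS2 2.1.1.20160309, STAR, HTSeq, DESeq2 1.22.1 and HiC-Pro 2.11.1, with no settings or order. The authors deposited, per replicate and for both replicates merged, peak lists in the MACS2 format; the series' design text states that merged files hold all replicates, and whether reads or peaks were merged is not given in the sources used here. In each deposited peak list the score is 10 times the -log10 q value as a whole number. The deposited fold of a peak is its enrichment over the local background as MACS2 writes it, and the control library behind it is not given in the sources used here. The -log10 values of p and q per peak are the authors', and the -log10 q exceeded 3 in all 6 lists. Peak folds and scores are the authors' own, and were used only to describe, rank or filter peaks within their list. The deposited fold change tables have the columns of DESeq2, per the file headers. The log2 fold change and its standard error in the deposited tables are the authors', and their ratio equalled the deposited Wald statistic for 100% of genes. The p-value and the adjusted p-value of each gene are the authors', per the file headers. The mean normalized count in the deposited tables is a mean signal over the libraries of a comparison, so that the sequencing depth of each sample is unknown and no interval from counting was computed. The labels do not name the control of the Pc mutant, and the table for ph does not name its control, which the labels give as white RNA interference. Libraries were made with a stranded kit per the labels' protocols, while the strand setting of the read counting is not given in the sources used here.

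Peaks were kept on the 6 chromosome arms. Overlap meant at least 1 shared bp, and was set against 1000 seeded shuffles of the peaks within their arm (one-sided permutation test, smallest possible p 0.000999). Summits were placed against the 17684 genes of the Release 6 annotation on these arms. That annotation was used as a table without strand, so the planned distance to start sites was replaced by a summit within 1000 bp of either end of a gene, and by a summit inside a gene. Genes were put in a binding class by a merged PSC or Su(z)12 peak in the gene body or the 1000 bp around it, which had been listed as the alternative to a window at start sites. Classes were compared with genes without a peak by Fisher's exact test (two-sided, Benjamini-Hochberg over 12 tests). Odds ratios have 95% intervals.

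Genes were called at the authors' adjusted p under 0.05. There were 12785 genes in the table for Pc, 11297 of them with an adjusted p, and 11771 in the table for ph, 11009 of them with an adjusted p. Of these, 12734 and 11728 genes were located in the annotation. Fold changes of the 2 comparisons were set against each other per gene by a z test of their difference, with the standard errors added in quadrature and Benjamini-Hochberg adjustment over 10588 genes. That test assumes that the comparisons share no library. Overlaps of calls were tested with Fisher's exact test (two-sided). The 22 gene lists, with 341 genes, were written before the data were examined: Hox genes, PRC1 subunits, PRC2 and PhoRC subunits, segmentation factors, appendage and antennal identity, retinal determination, photoreceptor and cone cell differentiation, the E(spl) complex, JAK/STAT, signalling ligands, JNK and wound response, cell cycle, ribosomal proteins, heat shock proteins, and markers of haemocytes, fat body, muscle, glia, brain neurons, salivary gland and gut, trachea and germline. Some genes stand in more than 1 list. A second muscle and a second fat body list, of genes in none of the others, were written later and before their values were looked up, for the closing section alone. Each list was tested with cameraPR of limma on the Wald statistic, at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. A correlation between genes cannot be estimated from tables without samples, so 0.05 was used as the alternative.

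The text names, by a rule fixed before the data were examined, every PRC1 subunit and Hox gene, the 5 genes with the largest increase and the 5 with the largest decrease among called genes with a mean count of at least 50, and up to 2 called members with the smallest adjusted p of every other list. The rule also takes the 5 peaks with the largest fold per protein and the 5 genes with the smallest adjusted p of the difference in each direction. Any other named gene is marked as chosen after its values were seen. The tests, thresholds, lists and most alternatives were also chosen before the data were examined. Alternatives tried were a reciprocal overlap of 50%, summits within 500 bp, peaks with a fold of at least 3, each replicate's list alone, an adjusted p under 0.01, a fold change of at least 2, a mean count of at least 50, comparison within 3 strata of mean count, ranks of the statistic and 10000 random lists matched on mean count. Added after seeing the data were centring on other medians, gene end windows and other windows around the gene, strata of gene length (for binding classes and for the binding of lists, by the Mantel-Haenszel test), the alternatives for overlaps of opposite calls, peaks found in both replicates for the overlap of the proteins, and leaving out genes on 3L.

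The steps were tested on simulated data. For the difference between the 2 perturbations (10588 genes), 55.22% of genes planted with a log2 difference of 1 were recovered, 82.09% at 2 and 84.85% at 4, and 6.918% of calls were unchanged genes. For the overlap of PSC and Su(z)12 peaks, randomly placed peaks gave a permutation p of 0.9453. Of 579 peaks planted at the starts of Su(z)12 peaks, 100% were found. That placement fixed the outcome, so it checks the counting and measures no sensitivity. For the binding classes (8464 genes), 4.5% of simulations were called at an odds ratio of 1 and 99% at 2. For the gene lists in the Pc comparison (11297 genes, 22 lists), 3 of 3 shifted lists and 0 of the others were called. The simulated statistics were independent between genes, so false calls among correlated genes were not tested. Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.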

Results

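The data describe the Polycomb system in eye discs, the larval tissue that forms the adult eye and antenna. PSC is a subunit of Polycomb repressive complex 1 (PRC1), and Su(z)12 is a subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Binding of both proteins was measured by ChIP-seq in 2 replicates each, as peak lists. Gene expression was measured by RNA-seq in discs mutant for Pc (2 replicates), in discs with RNA interference against ph (4 replicates) and in discs with RNA interference against white (4 replicates). The labels name the Pc mutant group Mutant_PcXT109_FRT2A. Whether all cells of these discs were mutant was not tested here, so values for the Pc mutant are averages over the disc. The labels do not say that replicates came from separate animals, so the p-values may measure technical spread. The design text names PRC1 during development as the subject of the series. The comparisons ask where PSC peaks lie with and without a Su(z)12 peak, and which genes respond to loss of a PRC1 subunit.

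PSC and Su(z)12 peaks were found at the same places in both replicates more often than uniform random placement along the arm gave. Such placement ignores which sequence is open or mappable, so part of the overlap may come from that. Of the PSC peaks of replicate 2, 86.28% (2774 of 3215) overlapped a peak of replicate 1, against a mean of 3.741% in shuffled lists. The reverse share was 48.31% of 5471 peaks, as the list of replicate 1 was longer. For Su(z)12, 75.08% of the 1196 peaks of replicate 2 lay in replicate 1 and 61.3% of 1434 peaks lay in the reverse direction, against 1.018% and 0.8401% in shuffled lists. All 4 permutation p-values were 0.000999, the smallest that 1000 shuffles can give. Of the 5999 merged PSC peaks, 2589 overlapped a peak in both replicates, 2490 in one and 920 in neither. Of the 2205 merged Su(z)12 peaks, 810 overlapped a peak in both replicates, 724 in one and 671 in neither.

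All 8 Hox genes, the homeotic selector genes that specify segment identity, carried peaks of both PSC and Su(z)12 in the merged lists. Antp (3R, 6896253 to 6999228, dm6) had 26 PSC and 42 Su(z)12 peaks in the gene and the 1000 bp around it. Ubx (3R, 16656623 to 16734426) had 16 and 35, Abd-B (3R, 16927212 to 16972236) had 13 and 35, and Scr (3R, 6823120 to 6849981) had 9 and 13. The fewest PSC peaks were at pb (3R, 6707800 to 6742063) and Dfd (3R, 6791836 to 6802428), with 3 each and 9 Su(z)12 peaks each. The gene lab (3R, 6661427 to 6678590) had 7 PSC and 3 Su(z)12 peaks, and abd-A (3R, 16807214 to 16830049) had 7 and 14. The number of peaks did not rank these genes by covered length. PSC peaks covered 4540 bp at pb, 2461 bp at Dfd, 4025 bp at lab and 4395 bp at abd-A.

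Several other lists, including developmental regulators and ribosomal protein genes, were also bound by both proteins more often than genes outside each list. The test was Fisher's exact test, adjusted over the 22 lists. Of the 26 genes of appendage and antennal identity, 20 had both (odds ratio 31.7, adjusted p = 1.23e-14). Both proteins were found at 17 of 32 segmentation factors (odds ratio 10.7, adjusted p = 7.5e-09), 8 of 12 retinal determination genes (18.8, adjusted p = 1.4e-05) and 10 of 21 photoreceptor genes (8.57, adjusted p = 3.87e-05). Of the PRC1 subunit genes, 4 of 7 had both (odds ratio 12.5, adjusted p = 0.00653), and the share was 10 of 30 for ribosomal protein genes (4.71, adjusted p = 0.00122), 5 of 11 for JAK/STAT genes (7.83, adjusted p = 0.00653) and 5 of 16 for JNK and wound genes (4.27, adjusted p = 0.0358). Within 3 strata of gene length (Mantel-Haenszel test) the odds ratio was 17.5 for appendage genes, 10.3 for segmentation factors, 10.9 for retinal determination genes, 4.53 for photoreceptor genes and 8.6 for ribosomal protein genes, with adjusted p-values of at most 0.00178. In these strata PRC1 subunit genes (7.72, adjusted p = 0.0537), JAK/STAT genes (4.28, adjusted p = 0.0985) and JNK and wound genes (3.1, adjusted p = 0.187) did not pass the test. Strata of mean count were not run for the binding of lists, so a part of expression level was not tested. Among tested genes of the Pc comparison, those with both proteins had a median mean count of 1732, against 252.5 for those without a peak. None of the 11 located E(spl) complex genes and none of the 11 PRC2 and PhoRC genes had both, although 7 of each list had PSC alone (upper limit of the odds ratio 3.73 for each, adjusted p = 0.703). Of all 13922 protein-coding genes, 1343 had both proteins, 2875 had PSC alone, 102 had Su(z)12 alone and 9602 had neither. Alone means that no peak of the other protein was called, which does not show its absence. The merged Su(z)12 list was shorter, with 2205 peaks against 5999. Among tested genes of the Pc comparison, 1249 had both in the merged lists, and 540 by peaks found in both replicates. By 1 replicate alone they were 835 (replicate 1) and 690 (replicate 2). The binding of lists was not rerun on these.

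The strongest PSC peak by fold, on 3R from 32067877 to 32069928, overlapped Map205. It ended 3093 bp before the last position of an annotated gene or listed peak on that arm. The next was on 3R from 16798413 to 16799155, with its summit 8358 bp from abd-A, followed by 3R from 6818801 to 6819981, with its summit 3739 bp from Scr. The other PSC peaks of the leading 5 were X from 2133749 to 2142114, overlapping the PRC1 gene ph-p and D2hgdh, and 3L from 21483549 to 21484547, with its summit 811 bp from Neu2. The strongest Su(z)12 peak lay on 3L from 19747 to 21109, with its summit 2455 bp from mthl8. It was followed by 2R from 1243243 to 1243946 (summit 20593 bp from CG40191), 2L from 5037 to 10031 (overlapping l(2)gl), 3L from 21483551 to 21484340 (769 bp from Neu2) and 3R from 6870833 to 6871243 (4778 bp from ftz). All 10 of these peaks overlapped a peak of the other protein.

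Across the genome, 25.42% of PSC peaks (1525 of 5999) overlapped a Su(z)12 peak, and 76.42% of Su(z)12 peaks (1685 of 2205) overlapped a PSC peak. Peaks were shuffled to any position of their arm, so the shuffles cannot separate shared targets from shared open or mappable sequence. Shuffled peaks gave a mean of 89.55 overlapping PSC peaks and a maximum of 118, so that the observed number was 17.0 times the mean (permutation p = 0.000999). This ratio depends on the lists and the rule for overlap: it was 30.6 with the lists of replicate 2 alone, 19.2 with those of replicate 1, 26.9 with merged peaks found in both replicates, 49.4 for a reciprocal overlap of at least 50%, 14.9 for summits within 500 bp and 102.3 for peaks with a fold of at least 3. The PSC peaks with Su(z)12 had a median width of 421 bp and a median fold of 2.43, against 302.5 bp and 1.88 for those without. A fold of at least 3 was reached by 21.97% of the former and 2.95% of the latter. Chromosome 4 had 131.8 PSC and 80.3 Su(z)12 peaks per Mb, while the other arms had between 38.2 (3L) and 53.0 (2L) PSC and between 9.52 (X) and 23.0 (3R) Su(z)12 peaks per Mb.

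**Figure D1:**
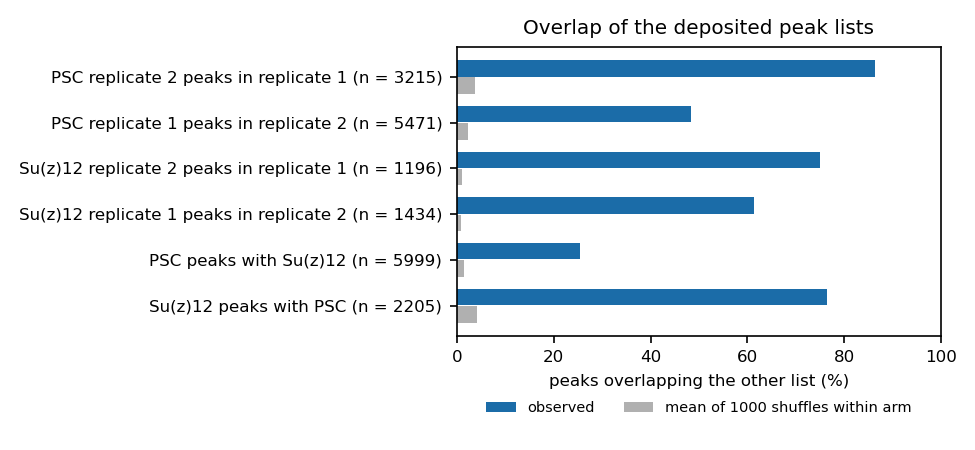
Share of peaks (percent) that overlap a peak of the other list, observed (blue) and as the mean of 1000 shuffles within the chromosome arm (grey), with the number of peaks in brackets. Observed shares run from 25.42% for PSC peaks with Su(z)12 to 86.28% for PSC replicate 2 in replicate 1, and shuffled means lie at or below 4.159%.

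Summits of PSC peaks with Su(z)12 lay inside annotated genes less often than those without: 37.05% against 56.06% (odds ratio 0.461, 95% interval 0.409 to 0.521, Fisher's exact test p = 8.49e-38). More of them lay outside genes and over 1000 bp from a gene end, 19.54% against 15.29% (odds ratio 1.35, exact p = 0.000139). The share within 1000 bp of a gene end was 58.56% against 55.21% (odds ratio 1.15, exact p = 0.0232). Among peaks with a fold of at least 3 that odds ratio was 0.629 (exact p = 0.0774), and with the lists of replicate 2 alone it was 1.05 (exact p = 0.603). Among peaks with a fold of at least 3 the odds ratio for summits outside genes was 1.15 (exact p = 0.762).

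In Pc mutant discs, 6 of the 8 Hox genes rose and genes of the developing retina fell. Pc, the chromodomain subunit of PRC1 (3L, 21306138 to 21318020), itself fell by 1.64 ± 0.41 on the log2 scale (± SE, adjusted p = 0.00134) in the authors' deposited table. Abd-B rose by 7.80 ± 0.38, Ubx by 5.97 ± 0.43, abd-A by 5.78 ± 0.53, Antp by 3.60 ± 0.47, pb by 2.53 ± 0.40 and Scr by 2.40 ± 0.40 in the authors' deposited table. The other Hox genes, lab and Dfd, had values of -0.48 ± 0.30 and -0.27 ± 0.15 in the authors' deposited table and were not called (adjusted p = 0.422 and 0.348). The ligands of JAK/STAT signalling upd1 (2.38 ± 0.25) and upd3 (3.47 ± 0.43) and the wound-induced hormone gene Ilp8 (6.41 ± 0.55) rose in the authors' deposited table.

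Among the other PRC1 subunits, Su(z)2, a relative of Psc, rose by 1.94 ± 0.23 (adjusted p = 1.27e-14) and ph-d fell by 0.38 ± 0.10 (adjusted p = 0.00175) in the authors' deposited table. Values for ph-p (-0.22), Psc (0.20), Sce (0.01) and Scm (0.02) did not pass the test in the authors' deposited table (adjusted p from 0.425 to 0.995). In all, 411 genes were called higher and 705 lower among 11297 in the authors' deposited table, so that 36.83% of calls were higher. After centring on the median of the ribosomal protein genes (a shift of 0.07), 309 were higher and 963 lower, or 24.29% higher.

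The largest increases in the authors' deposited table were those of CG4382 (7.98 ± 0.79), Abd-B, the pigment gene y (7.18 ± 0.33), the transcription factor gene Sox15 (6.60 ± 0.50) and Ilp8. The largest decreases in the authors' deposited table were those of CG34461 (-7.13 ± 1.18), Tektin-C (-6.40 ± 0.32) and the cuticle protein genes Cpr92F (-5.60 ± 1.25), Cpr62Bc (-5.48 ± 1.18) and Cpr49Ae (-5.43 ± 0.94). Adjusted p-values of these 10 genes in the authors' deposited table were at most 0.000264. Genes on 3L, the arm that carries Pc, were called more often than others, 13.31% against 9.003%.

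The Hox list moved up as a set (6 of 8 called, also 6 adjusted over the list alone, adjusted p = 6.47e-30 by cameraPR). For all list tests here the correlation between genes is preset and could not be estimated. Of 11 JAK/STAT genes, 6 were higher and 0 lower, with 7 higher adjusted over the list alone (adjusted p = 1.43e-10) and 4 higher after centring on the ribosomal protein median. JNK and wound genes had 6 of 16 higher and 2 lower, and 8 and 3 adjusted over the list alone (adjusted p = 1.71e-05). Mmp1, a matrix metalloprotease gene, rose by 1.68 ± 0.16 in the authors' deposited table. Among segmentation factors, 7 of 31 were higher and 2 lower, the same numbers adjusted over the list alone, with Kr (3.96 ± 0.42) and kni (0.88 ± 0.12) the clearest in the authors' deposited table. That list's adjusted p was 0.0506, its mean was 0.35 and its median was -0.02.

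Retinal genes moved down. Of 12 retinal determination genes, 8 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 2.42e-06), with dan at -1.42 ± 0.28 and tsh, which acts in the body wall and the anterior eye, at 1.09 ± 0.17 in the authors' deposited table. The eye genes eya (-1.03), so (-0.70), toy (-1.07) and ey (-0.86), named after their values were seen, fell in the authors' deposited table. Of 21 photoreceptor and cone cell genes, 15 were lower and 0 higher, and 19 and 1 adjusted over the list alone (adjusted p = 3.5e-15), with the neuronal gene elav at -0.86 ± 0.13 and sca at -0.68 ± 0.11 in the authors' deposited table. Of 11 E(spl) complex genes, which are targets of Notch, 7 were lower and 0 higher, and 8 and 1 adjusted over the list alone (adjusted p = 5.85e-06), with E(spl)m5-HLH at -1.45 ± 0.31 and E(spl)m4-BFM at -1.23 ± 0.24 in the authors' deposited table.

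Genes of appendage and antennal identity moved both ways: 5 of 26 were higher and 6 lower, and 6 and 11 adjusted over the list alone (adjusted p = 0.828, median -0.14, mean 0.09). After centring, 4 were higher, and 8 lower on the median of all genes or 11 lower on the ribosomal protein median. The wing genes vg (3.58 ± 0.37) and ap (2.61 ± 0.26) rose in the authors' deposited table. Signalling ligands had 4 of 17 higher and 3 lower, and 4 and 4 adjusted over the list alone (adjusted p = 0.917, median -0.04, mean 0.01), and the lower ones included hh (-0.50 ± 0.12) and Dl (-0.43 ± 0.09) in the authors' deposited table. Of 27 cell cycle genes, 1 was higher (Mcm5, 0.66 ± 0.11 in the authors' deposited table) and 2 lower, among them dap (-0.47 ± 0.10), the same adjusted over the list alone. That list had an adjusted p of 0.944, and its median was 0.03 and its mean -0.01. None of the 30 ribosomal protein genes, 11 PRC2 and PhoRC genes or 12 heat shock genes was called, over all genes or adjusted over the list alone (adjusted p = 0.129, 0.432 and 0.353). The PRC1 list had 1 higher and 2 lower of 7, the same adjusted over the list alone (adjusted p = 0.944, direction up, median 0.01, mean -0.01).

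Lists written as markers of cell types other than the disc epithelium moved in the same table. Whether their members are also expressed in the disc epithelium was not tested, so a fall need not mean fewer of those cells. Of 17 muscle markers, 14 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 1.67e-11, median -1.53), with Mlc2 at -1.68 ± 0.31 and bt at -1.61 ± 0.31 in the authors' deposited table. Of 14 fat body markers, 6 were lower and 0 higher, and 7 and 0 adjusted over the list alone (adjusted p = 0.000241), with apolpp at -1.96 ± 0.51 and Lsp1gamma at -2.85 ± 0.78 in the authors' deposited table. Brain neuron markers had 2 of 14 lower and 0 higher, and 5 and 0 adjusted over the list alone (adjusted p = 0.000723), with Rdl at -1.45 ± 0.35 and dpn at -0.73 ± 0.16 in the authors' deposited table. Glia markers had 2 of 10 lower, Gli (-0.25 ± 0.06) and loco (-0.34 ± 0.08) in the authors' deposited table, and also 2 adjusted over the list alone (adjusted p = 0.0385, and adjusted p = 0.0848 at a preset correlation of 0.05). The salivary gland and gut list was up as a set (adjusted p = 0.00303, median 2.79) although 0 of its 13 members were called over all genes and 3 adjusted over the list alone.

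Haemocyte markers had 1 of 15 higher and 2 lower, lz (-0.94 ± 0.16) and atilla (-0.56 ± 0.13) in the authors' deposited table, and 2 and 2 adjusted over the list alone (adjusted p = 0.671, median 0.02, mean -0.04). Trachea markers had 1 of 7 higher (trh, 1.58 ± 0.36) and 1 lower (Gasp, -0.72 ± 0.11) in the authors' deposited table, and 2 and 1 adjusted over the list alone (adjusted p = 0.843). Germline genes had 0 of 15 higher and 3 lower, including vas (-1.68 ± 0.34) and spn-E (-0.66 ± 0.19) in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.432, median 0.02, mean -0.08). After centring on the ribosomal protein median, the medians of PRC1 (-0.07), PRC2 and PhoRC (-0.06), cell cycle (-0.04), haemocyte (-0.06) and germline genes (-0.05) turned negative.

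In discs with RNA interference against ph, most of the genes of the developing retina fell, and 6 of the 8 Hox genes rose while 2 fell. The targeted genes ph-p and ph-d, neighbouring copies that encode the polyhomeotic subunit of PRC1 (X, 2126210 to 2138371 and 2115727 to 2123286), fell by 0.80 ± 0.04 and 0.66 ± 0.05 on the log2 scale (adjusted p = 1.11e-88 and 6.9e-42) in the authors' deposited table. Reads of these near-identical copies may be split between them. Abd-B rose by 8.99 ± 0.16, abd-A by 7.82 ± 0.69, Ubx by 5.44 ± 0.20, Antp by 5.22 ± 0.94, pb by 4.63 ± 0.22 and Scr by 2.49 ± 0.44 in the authors' deposited table. The head Hox genes lab and Dfd fell by 3.47 ± 0.16 and 0.24 ± 0.06 in the authors' deposited table.

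The largest increases in the authors' deposited table were those of the posterior and segmentation genes cad (9.77 ± 0.41), eve (9.64 ± 0.66) and byn (9.07 ± 1.04), of mthl8 (9.16 ± 0.55) and of Abd-B. The gene mthl8 is the coding gene nearest to the strongest Su(z)12 peak. The largest decreases in the authors' deposited table were those of the nuclear receptor gene Hr3 (-9.14 ± 1.07), dpr5 (-8.58 ± 1.05), CG9021 (-8.54 ± 1.72), Osi7 (-8.42 ± 0.60) and the cuticle protein gene Cpr72Ea (-8.39 ± 1.05). Among PRC1 subunits, Su(z)2 rose by 3.51 ± 0.09, Psc rose by 1.59 ± 0.07 and Pc fell by 0.14 ± 0.07 (adjusted p = 0.0453 for Pc) in the authors' deposited table. Sce (-0.06) and Scm (-0.05) were not called in the authors' deposited table (adjusted p = 0.235 and 0.457). After centring on the median of all genes, the value of Pc was -0.08 (adjusted p = 0.281). After centring on the ribosomal protein median, Sce (-0.45, adjusted p = 1.2e-24) and Scm (-0.44, adjusted p = 1.895e-15) were called lower. The gene w, the target of the control RNA interference and named after its value was seen, rose by 0.79 ± 0.12 in the authors' deposited table.

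**Figure D2:**
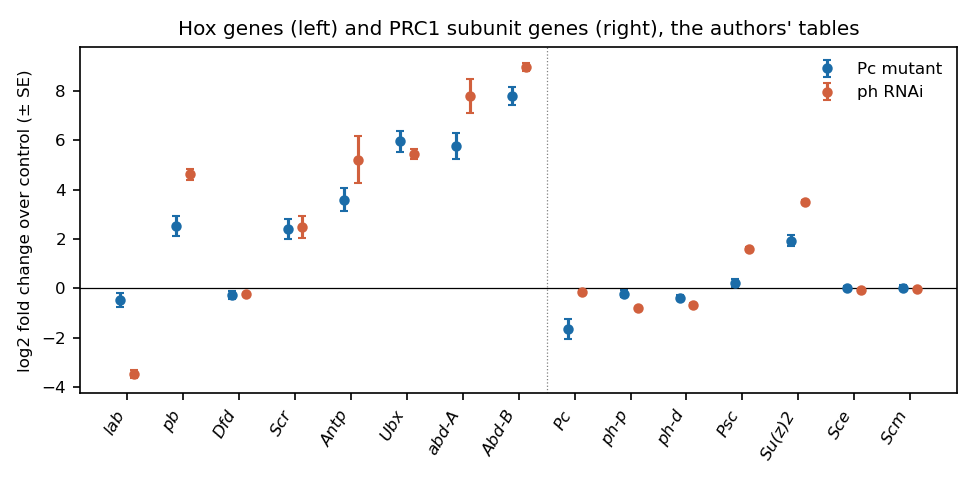
Log2 fold change over control with its standard error for the 8 Hox genes and the 7 PRC1 subunit genes in the authors' deposited tables for the Pc mutant (blue) and ph RNA interference (orange). Abd-B lies highest in both tables, at 7.80 and 8.99, while lab lies at -0.48 and -3.47.

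Of 11009 genes, 3421 were called higher and 3845 lower in the authors' deposited table, or 47.08% higher. Among calls of at least 2-fold, 556 were higher and 2140 lower, or 20.62% higher. Centred on the median of the ribosomal protein genes, a shift of 0.39, 1417 genes were higher and 6207 lower, or 18.59% higher. The balance turned when centred on the median of all genes, with 3774 higher and 3531 lower (51.66% higher), and among genes with a mean count of at least 50, with 3240 and 2978 (52.11%). Values and directions in this comparison are therefore relative to the authors' own normalization, and lists whose median turns under another centring are named.

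Retinal lists moved down. All 21 photoreceptor and cone cell genes were lower, also adjusted over the list alone (adjusted p = 9.28e-12, median -4.17), among them elav (-1.76 ± 0.05) and oc (-1.40 ± 0.04) in the authors' deposited table. Of 12 retinal determination genes, 11 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 7.94e-07), with dan at -2.13 ± 0.09 and tio at -2.39 ± 0.09 in the authors' deposited table. The higher gene was Optix (0.84 ± 0.07), and eya (-5.33 ± 1.04), so (-3.60 ± 0.24), ato (-4.58 ± 0.54) and gl (-5.87) were among the lower, all 5 named after their values in the authors' deposited table were seen. Of 11 E(spl) complex genes, 9 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 6.28e-06), with E(spl)m2-BFM at -2.63 ± 0.09 and E(spl)mgamma-HLH at -2.91 ± 0.11 in the authors' deposited table. Of 26 genes of appendage and antennal identity, 18 were lower and 6 higher, the same adjusted over the list alone (adjusted p = 0.000172), with B-H2 at -3.31 ± 0.08 and vg at 4.87 ± 0.10 in the authors' deposited table.

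The Hox list moved up (6 higher and 2 lower of 8, the same adjusted over the list alone, adjusted p = 0.000284), and its adjusted p was 0.0668 on ranks of the statistic. Of 11 JAK/STAT genes, 8 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.00244), with chinmo at 2.99 ± 0.09 and Stat92E at 0.67 ± 0.02 in the authors' deposited table. After the ribosomal shift, 6 JAK/STAT genes were higher and 4 lower, with a median of 0.27. Of 27 cell cycle genes, 23 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 3.75e-20, median 0.61), including the replication genes dup (1.47 ± 0.03) and Mcm5 (1.51 ± 0.04) in the authors' deposited table. After the ribosomal shift, 16 cell cycle genes were higher and 6 lower, with a median of 0.22. All 30 ribosomal protein genes were higher, also adjusted over the list alone (adjusted p = 2.57e-20, median 0.39), including RpL13 (0.44 ± 0.02) and RpS13 (0.38 ± 0.01) in the authors' deposited table. After the ribosomal shift, 6 of them were higher and 3 lower. Of 11 PRC2 and PhoRC genes, 7 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0173), with esc at 1.52 ± 0.06 and Caf1-55 at 0.61 ± 0.03 in the authors' deposited table. After the ribosomal shift that list had 3 higher and 7 lower and its median turned to -0.18, while the set test lost its call (adjusted p = 0.484, direction up), and its adjusted p was 0.0502 at a preset correlation of 0.05.

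Among segmentation factors, 11 of 31 were higher and 12 lower, the same adjusted over the list alone, with slp2 at -4.08 ± 0.17 in the authors' deposited table (adjusted p = 0.816, median -0.36, mean 0.33). Signalling ligands had 5 of 17 higher and 12 lower, the same adjusted over the list alone (adjusted p = 0.277), with wg at 1.62 ± 0.04 and Dl at -1.31 ± 0.04 in the authors' deposited table. JNK and wound genes had 8 of 16 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.408), with the apoptosis gene rpr at 1.97 ± 0.10 in the authors' deposited table. Heat shock genes had 2 of 12 higher and 2 lower, and 1 and 2 adjusted over the list alone (adjusted p = 0.816, direction down, median -0.04, mean 0.0013), with Hsp70Bb at 1.64 ± 0.07 and Hsp27 at -2.14 ± 0.10 in the authors' deposited table, and 1 higher and 4 lower after the ribosomal shift. The PRC1 list had 2 higher and 3 lower of 7, the same adjusted over the list alone (adjusted p = 0.363, direction up, median -0.06, mean 0.48), and 2 higher and 5 lower after that shift. Centred on the median of all genes, the medians of PRC1 and heat shock genes turned to 0.0028 and 0.025.

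Lists written as markers of other cell types also moved, and expression of their members in the disc epithelium was not tested here either. The mean counts of grh (13336) and lz (2135) were above the median of 481.8 over all listed genes. Brain neuron markers had 11 of 14 lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.00966, median -4.22), with Rdl at -4.33 ± 0.33 and grh at -1.15 ± 0.05 in the authors' deposited table. After the ribosomal shift 11 were lower with a median of -4.61, while the set test, which compares the list with the other genes, gave an adjusted p of 0.182. Trachea markers had 5 of 7 lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0282, and 0.0532 at a preset correlation of 0.05), with Gasp at -1.35 ± 0.05 and trh at 4.77 ± 0.21 in the authors' deposited table. Haemocyte markers had 13 of 15 lower and 1 higher, the same adjusted over the list alone, while the set test gave an adjusted p of 0.261 (0.0216 on ranks). Their called members included lz (-5.38 ± 0.72) and Ppn (0.81 ± 0.08) in the authors' deposited table. Muscle markers had 7 of 17 lower and 1 higher, and 6 and 1 adjusted over the list alone (adjusted p = 0.451), with sls at -2.07 ± 0.11 and Tm1 at 0.19 ± 0.03 in the authors' deposited table, the latter -0.21 after the ribosomal shift, when 11 muscle markers were lower and 0 higher.

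Glia markers had 4 of 10 higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.677), with nrv2 at 0.48 ± 0.02 and Gli at -1.31 ± 0.05 in the authors' deposited table. Fat body markers had 1 of 14 higher (FASN1, 3.28 ± 0.08) and 2 lower, including Yp2 (-1.63 ± 0.45), in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.335). Salivary gland and gut markers had 1 of 5 lower (Sgs8, -2.79) in the authors' deposited table and 0 adjusted over the list alone (adjusted p = 0.816). Germline genes had 4 of 14 higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.246, direction up, median 0.02, mean -0.32), with mael at 4.86 ± 0.12 and vret at 1.35 ± 0.07 in the authors' deposited table. The germline median turned to -0.07 when centred on genes with a mean count of at least 500 and to -0.38 after the ribosomal shift (3 higher and 8 lower), where the set test called the list up relative to other genes (adjusted p = 0.0261).

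**Figure D3:**
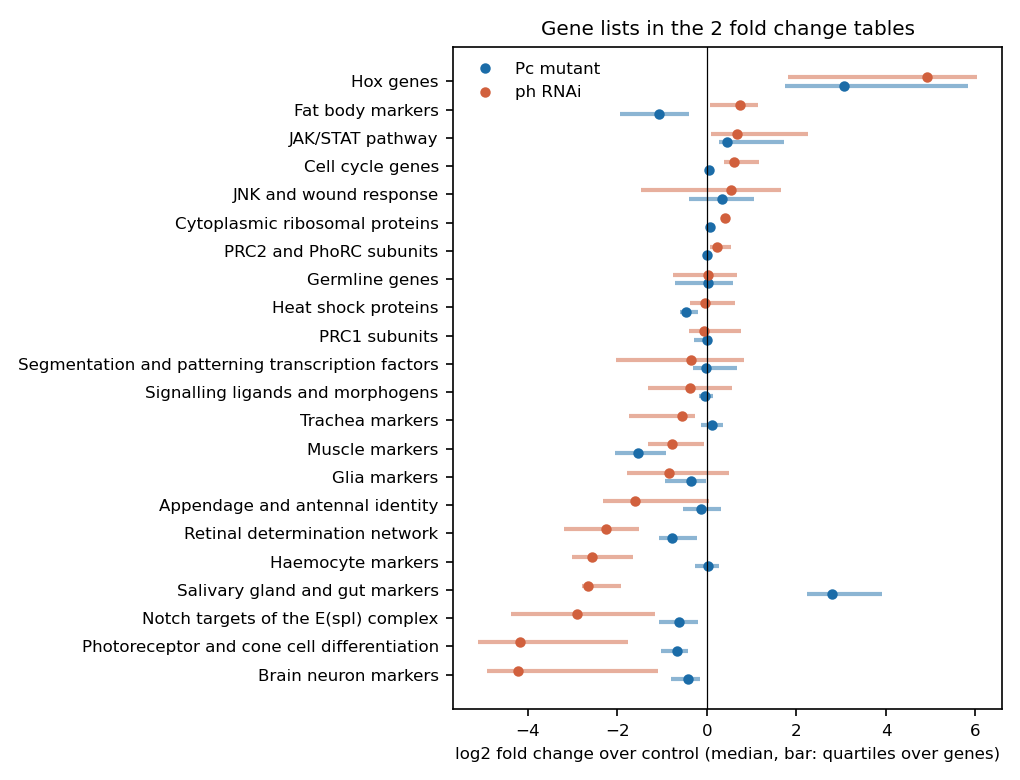
Median log2 fold change over control (points) and quartiles over genes (bars) of the 22 gene lists in the authors' deposited tables for the Pc mutant (blue) and ph RNA interference (orange). The Hox list has the highest median in both, at 3.07 and 4.92; under the ribosomal shift the PRC2 and PhoRC and the germline medians of ph RNA interference turn negative and the ribosomal median becomes 0.

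Genes that fell in Pc mutant discs mostly fell in ph RNA interference discs too, and the Hox genes Abd-B, abd-A, Ubx, Antp, pb and Scr rose in both. Over 10588 genes with an adjusted p in both of the authors' deposited tables, 680 were lower in the Pc mutant and 491 of these were lower in ph RNA interference, against 245 for independent lists (odds ratio 5.15, 95% interval 4.32 to 6.15, Fisher's exact test p = 1.86e-87). Of 391 genes higher in the Pc mutant, 170 were higher in ph RNA interference, against 125.9 (odds ratio 1.65, 1.34 to 2.04, exact p = 1.94e-06). Among calls of at least 2-fold 45 genes were higher in both, against 7.707 (odds ratio 8.54), and 47 were higher in the Pc mutant and lower in ph RNA interference, against 29.89 (odds ratio 1.85, exact p = 0.000893). Across genes, which are not independent replicates, Spearman's rho between the fold changes was 0.234 and Pearson's r was 0.147. Whether the comparisons share control libraries is not given in the sources used here, and part of the overlap may come from such sharing.

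The perturbations also differed at single genes. By the test of the difference, 2906 genes were higher in the Pc mutant relative to ph RNA interference and 2372 lower, and 4631 and 938 with each table centred on its ribosomal protein median. With each table centred on its own median the balance turned, to 2648 higher and 2773 lower. The clearest differences towards the Pc mutant were at mth (3L, 343378 to 346957), y (X, 356509 to 361245), CG10359 (3L), unc-5 (2R) and chp (3R). In the authors' deposited tables mth was at 2.39 ± 0.10 in the Pc mutant and -0.96 ± 0.03 in ph RNA interference, and y was at 7.18 ± 0.33 and -4.21 ± 0.16. The guidance receptor gene unc-5 (-0.12 and -3.15) and the photoreceptor gene chp (-0.03 and -3.49) were called in ph RNA interference and not in the Pc mutant in the authors' deposited tables, although unc-5 was called lower in the Pc mutant after the ribosomal shift (-0.19, adjusted p = 0.0289). The clearest differences towards ph RNA interference were at pst (3L, 7357275 to 7360263), FASN1, mael, CG4096 and CG7432. The authors' deposited tables gave pst as -1.63 ± 0.08 in the Pc mutant and 2.00 ± 0.04 in ph RNA interference. The fatty acid synthase gene FASN1 (-0.34 and 3.28), the piRNA pathway gene mael (0.02 and 4.86), CG4096 (-0.33 and 2.84) and CG7432 (-0.48 and 3.72) were called in ph RNA interference and not in the Pc mutant in the authors' deposited tables. After the ribosomal shift FASN1 (-0.41, adjusted p = 0.0227) and CG7432 (-0.55, adjusted p = 0.0197) were called lower in the Pc mutant, and CG7432 also when centred on all genes (adjusted p = 0.0497) or on genes with a mean count of at least 500 (adjusted p = 0.0492).

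By list, the difference of the statistics was lower in ph RNA interference for photoreceptor genes (adjusted p = 4.87e-10), E(spl) complex genes (3.52e-06), appendage genes (5.22e-06), retinal determination genes (6.59e-05) and brain neuron markers (0.00324). It was higher in ph RNA interference for cell cycle genes (adjusted p = 5.04e-11), ribosomal protein genes (0.000159), fat body markers (0.0172, and 0.0651 at a preset correlation of 0.05) and PRC2 and PhoRC genes (0.0436, and 0.104). Centring on the ribosomal protein median was not run for these list differences. In ph RNA interference alone, that centring set the ribosomal median to 0 and turned the PRC2 and PhoRC median to -0.18. Hox genes (adjusted p = 0.698), JAK/STAT genes (0.308) and muscle markers (0.308) did not pass this test. The other lists, heat shock genes (0.707), PRC1 subunits, segmentation factors (both 0.308), signalling ligands (0.196), JNK and wound genes (0.984) and markers of haemocytes (0.109), glia (0.698), salivary gland and gut (0.528), trachea (0.0945) and germline (0.0618), did not pass it either.

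Genes bound by both PSC and Su(z)12, among them the 6 Hox genes that rose, were called higher in the Pc mutant more often than genes without a peak. The share was 6.165% (77 of 1249) against 3.063% (221 of 7215), an odds ratio of 2.08 (95% interval 1.57 to 2.73, Fisher's exact test, adjusted p = 1.29e-06). It was 1.68 among calls of at least 2-fold. Genes with PSC alone had 3.982% higher (odds ratio 1.31, adjusted p = 0.0366) and 7.633% lower (1.42, adjusted p = 0.000213), and genes with both had 7.606% lower (1.42, adjusted p = 0.00707). Of the 79 genes with Su(z)12 alone, 2 were higher and 6 lower (adjusted p = 1 and 0.54). At 2-fold or more the odds ratio of PSC alone for higher genes was 0.482, and those for lower genes were 0.456 for both proteins and 0.52 for PSC alone. With the lists of replicate 2 alone, the odds ratios of PSC alone were 1.23 for higher genes (adjusted p = 0.182) and 1.04 for lower genes (adjusted p = 0.718), and within 3 strata of gene length that of both proteins for lower genes was 0.964. Within 3 strata of mean count or of gene length, PSC alone had no call for higher genes (Mantel-Haenszel test, adjusted p = 0.339 and 0.454).

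In ph RNA interference, 44.95% of genes with both proteins and 40.08% of those with PSC alone were lower, against 30.9% of genes without a peak (odds ratios 1.83 and 1.5, adjusted p = 2.65e-20 and 1.2e-16). Of the 80 genes with Su(z)12 alone, 43 were lower (odds ratio 2.6, adjusted p = 6.47e-05) and 25 higher (1.13, adjusted p = 0.676). Higher genes made up 33.63% of genes with both and 36.01% of those with PSC alone, against 28.68% (odds ratios 1.26 and 1.4, adjusted p = 0.000834 and 1.61e-11). Genes with both proteins had a median length of 6.24 kb and a median mean count of 2169, against 2.15 kb and 206.9 for genes without a peak in the authors' deposited table. Within 3 strata of mean count, the odds ratios for higher genes were 0.653 and 0.758, and at 2-fold or more those for lower genes were 0.82 and 0.825. Within 3 strata of gene length, those for lower genes were 1.18 (adjusted p = 0.0398) and 1.1 (adjusted p = 0.105). With the lists of replicate 1 alone, the odds ratio of PSC alone for higher genes was 1.11 (adjusted p = 0.05001) and that of Su(z)12 alone for lower genes was 1.43 (adjusted p = 0.247).

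**Figure D4:**
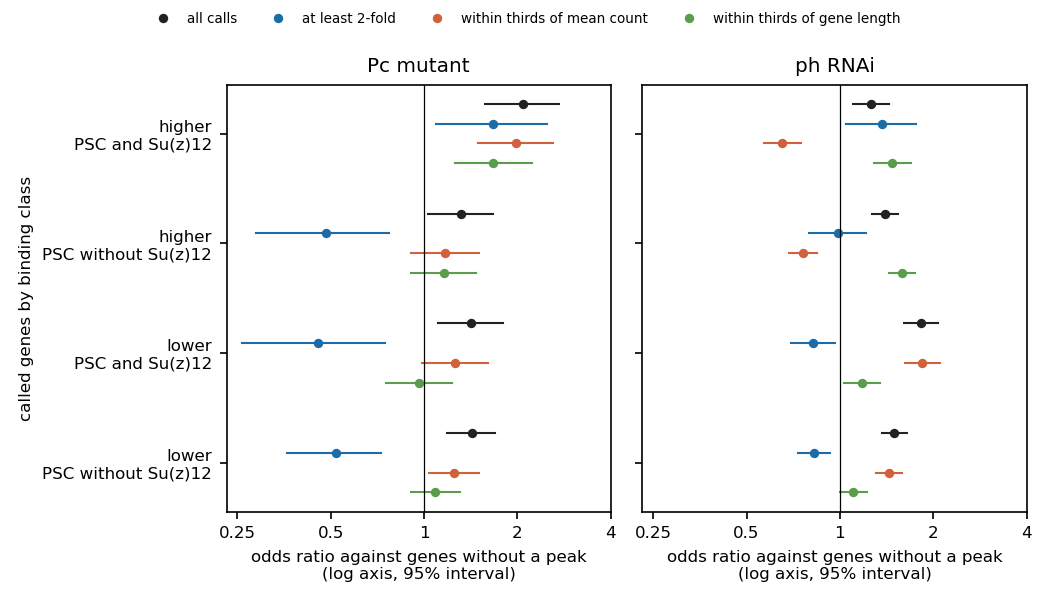
Odds ratio (log axis, 95% interval) of a called gene in genes with PSC and Su(z)12 or with PSC alone, against genes without a peak, for the Pc mutant (left) and ph RNA interference (right), over all calls, calls of at least 2-fold, and within 3 strata of mean count or gene length. Higher genes with both proteins in the Pc mutant lie above 1 in each setting drawn (2.08 over all calls, 1.68 at 2-fold), while those in ph RNA interference fall to 0.653 within strata of mean count.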

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

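The tests of expression level and of PSC peaks in the paragraph on muscle and fat body were chosen after the result was seen. Those of the second lists there and those on 3L were written before their values were computed, though both patterns were first noticed in the data. The second lists replaced an earlier test that used the muscle markers themselves and so repeated the pattern it was meant to test.

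Several genes went in opposite directions in the 2 perturbations, by the test of the difference. The log2 fold change in the Pc mutant minus that in ph RNA interference, from the authors' deposited tables, was 11.39 ± 0.37 at y, 3.35 ± 0.11 at mth and 5.01 ± 0.20 at CG10359, and -3.64 ± 0.09 at pst. In all, 144 genes were called higher in the Pc mutant and lower in ph RNA interference, against 140.9 for independent lists, and 49 genes were called lower in the Pc mutant and higher in ph RNA interference, against 218.9. At 2-fold or more these were 47 against 29.89 (exact p = 0.000893) and 8 against 12.79 (exact p = 0.191).

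Of these genes mth, CG10359 and pst lie on 3L, the arm that carries Pc. If genes of 3L responded more often to loss of either subunit, they would be called more often in ph RNA interference too. The odds ratio of a call on 3L there was 0.892 (95% interval 0.809 to 0.985, Fisher's exact test p = 0.0235), below the interval of the Pc mutant. Most genes were called there, 63.91% on 3L against 66.49% elsewhere. The ratio therefore shows no excess over all calls, and cannot exclude one among genes that respond in both. Variants linked to the mutation on 3L remain a candidate explanation for part of the calls: in the Pc mutant the odds ratio was 1.55 (1.34 to 1.79, exact p = 2.24e-09), with 305 of 2291 genes called. The control strain is not given in the sources used here, so differences between strains on the other arms stay open, and so does an effect of Pc on these genes. For y, on X, no explanation was tested.

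Fat body markers differed between the perturbations (adjusted p = 0.0172, and 0.0651 at a preset correlation of 0.05) and, with muscle markers, were lower in the Pc mutant. A trend with expression level was argued against for both, as the median of each list lay at percentile 0 of 10000 lists matched on mean count. Fewer muscle cells in the Pc mutant libraries may account for the muscle part: of 15 tested genes of the second muscle list 9 were lower and 0 higher in the authors' deposited table, with a median of -1.17 (quartiles -1.45 and -0.17), although Tm1 (-0.06) and Mef2 (0.10), named after their values were seen, were not lower. Fewer fat body cells stay open, as 2 of 10 tested genes of the second fat body list were lower in the authors' deposited table, with a median of -0.33 (quartiles -0.86 and -0.29), and so does binding of muscle genes, with a PSC peak at 5 of 17 (odds ratio 0.767, interval 0.212 to 2.34, exact p = 0.801). A lower level of these transcripts in unchanged numbers of cells would lower the same lists and was not tested.

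The peak list of Su(z)12 replicate 2 held 6 peaks on the mitochondrial genome, outside the arms compared. The authors' deposited table for ph RNA interference listed 77 genes with a fold change and no p-value. Of 14 antimicrobial peptide genes, picked by hand after the values were seen, 9 were among those genes.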

How the results depend on the processing

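Centring on other medians, windows other than 1000 bp, strata of gene length, leaving out genes on 3L and all alternatives for opposite calls were chosen after seeing the data. There were 201 alternative values for 34 results that answer a comparison. Of these, 154 either kept their direction and side of the threshold or were counts that moved by at most 1.5 times. For such counts, which direction had more genes was not checked in this tally. Of the rest, 19 lost the call, 1 gained it, 10 were counts that moved by over 1.5 times and 17 turned in direction. For 220 results on single lists and genes, 808 of 906 values kept their direction and side of the threshold, 45 lost the call, 23 gained it and 30 turned. The genes among them were in part chosen for a small adjusted p or a large fold change. At stricter thresholds their direction could not turn, so the share kept does not measure robustness. The overlaps of peak lists and those of calls in the same direction kept their direction and call under each alternative run. The cause was not tested except where named.

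Counts of genes in the Pc mutant were 255 higher and 452 lower at an adjusted p under 0.01, and 170 and 274 at a fold change of at least 2, where fewer genes can pass. In ph RNA interference they were 556 and 2140 at a fold change of at least 2, and 1417 and 6207 centred on ribosomal proteins. So centred, the difference between perturbations gave 4631 genes higher and 938 lower in the Pc mutant. Counts that moved less still changed which direction had more genes: the difference had 2648 higher and 2773 lower with each table centred on its own median, and ph had 3774 and 3531 centred on all genes, and 3240 and 2978 at a mean count of at least 50. For genes higher in the Pc mutant and lower in ph, the odds ratio was 1.85 at a fold change of at least 2, 0.998 at a mean count of at least 50 and 0.959 without genes on 3L. For genes lower in the Pc mutant and higher in ph it was 0.607 at a fold change of at least 2.

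For PSC summits with against without Su(z)12, the odds ratio near a gene end was 0.629 at a fold of at least 3 and 1.05 to 1.38 with a replicate left out. Outside genes it was 1.15 at a fold of at least 3.

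In the Pc mutant, the odds ratio of PSC alone for higher genes was 1.2 with 2000 bp, 1.24 at gene ends, 1.3 with peaks of both replicates, 1.17 in strata of mean count, 1.16 in strata of length, 0.482 at 2-fold, and 1.23 to 1.61 with a replicate left out. Its call was lost in each of these except at 2-fold, where it turned, and with replicate 1 alone (Fisher's exact or Mantel-Haenszel test, adjusted p of the lost calls from 0.099 to 0.454). For lower genes, both proteins gave 1.25 with 2000 bp, 1.29 at gene ends, 1.26 in strata of mean count, 0.964 in strata of length and 0.456 at 2-fold. All but the last had no call (the same tests, adjusted p from 0.0744 to 0.966). PSC alone gave 1.15 with peaks of both replicates, 1.09 in strata of length, 0.52 at 2-fold and 1.04 to 1.78 with a replicate left out. It lost the call with peaks of both replicates, in strata of length and with replicate 2 alone (the same tests, adjusted p from 0.24 to 0.718). Su(z)12 alone gave 0.944 with 500 bp, and 0 to 1.57 with a replicate left out.

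In ph RNA interference, both proteins gave for higher genes 1.2 with peaks of both replicates (call lost, Fisher's exact test, adjusted p = 0.0908) and 0.653 in strata of mean count. PSC alone gave 0.985 at 2-fold, 0.758 in strata of mean count and 1.11 to 1.5 with a replicate left out. Su(z)12 alone gave 0.902 with 2000 bp, 0.247 at 2-fold and 0.804 in strata of mean count. For lower genes, both proteins gave 0.82 at 2-fold, PSC alone 0.825 at 2-fold and 1.1 in strata of length, and Su(z)12 alone 1.43 to 1.65 with a replicate left out.

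Lists whose set test turned in direction had no call before or after. On ranks, the adjusted p was 0.701 (Pc mutant) and 0.842 (ph) for PRC1, 0.979 for heat shock genes in ph and 0.971 for JNK genes in the difference. Centred on ribosomal proteins it was 0.989 for PRC1 in the Pc mutant, and in ph 0.409 for segmentation, 0.543 for heat shock, 0.933 for muscle and 0.532 for salivary gland lists. Percentiles among matched lists on the other side of the middle were, in the Pc mutant, 39.4 (PRC1), 44.4 (PRC2 and PhoRC), 35.3 (segmentation), 70.3 (cell cycle), 54.4 (haemocytes) and 64.7 (germline), and 29.7 for PRC1 in ph. Within strata of length, the odds ratio of both proteins was 1.06 for heat shock genes, 0.924 for muscle and 0.851 for brain neuron markers, none of them called, and Hox genes gave no value as all had both.

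Lists gained a call in the Pc mutant for segmentation factors centred on ribosomal proteins (adjusted p = 0.0116) and ribosomal proteins on ranks (0.0126), and as percentiles among matched lists for appendage (0), heat shock (0.01) and ribosomal protein genes (99.1). In ph they did so centred on ribosomal proteins for fat body (adjusted p = 0.0238) and germline lists (0.0261), on ranks for haemocytes (0.0216), and as percentiles for signalling ligands (0.55), JNK genes (99.9), haemocytes (0), fat body (99.99) and muscle (1.58). In the difference, haemocytes gained one on ranks (adjusted p = 0.00602).

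Of single genes, in log2, Sce in the Pc mutant was -0.0119 centred on all genes, -0.0128 on genes with a mean count of at least 500 and -0.0675 on ribosomal proteins, and Scm was -0.001905, -0.002775 and -0.05745. In ph, centred on all genes, Sce was 0.0028 and Scm 0.0134. Centred on ribosomal proteins, mael was -0.0488 in the Pc mutant, and RpS13 -0.0185 and Tm1 -0.2087 in ph. Of these, Tm1 was called both before and after it turned (adjusted p = 1.6e-09 and 9.25e-12). In ph, Sce and Scm gained a call when centred on genes with a mean count of at least 500 (-0.147 and -0.136) and on ribosomal proteins (-0.453 and -0.443), and in the Pc mutant CG7432 gained one under all 3 centrings and unc-5 and FASN1 under the last.

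No paired analysis was possible because the fold change tables hold no values per sample and the peak overlaps come from no model. For the same reason a replicate block, leaving out RNA replicates, other tools and other splits of the samples were not run. Distances of 500 and 2000 bp to start sites were not run, as the annotation was used without strand. Depth is unknown for all samples.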

Other observations

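The tests in this part were chosen after the patterns were seen, although the values expected of the standard errors of photoreceptor genes were written before those were computed. That these errors decide nothing when most matched genes are called lower was set after the values were seen.

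Families were taken by the start of the gene symbol, 38 per table, and tested with cameraPR, and in ph RNA interference 6 of them were called up relative to the other genes. They were Rp (95 genes, median log2 fold change 0.39, adjusted p = 1.64e-30), the mitochondrial ribosomal proteins mRp (72 genes, 0.51, adjusted p = 3.09e-08), the nucleoporins Nup (19 genes, 0.60, adjusted p = 2.36e-09), the initiation factors eI (39 genes, 0.32, adjusted p = 3.84e-06), the subunits of NADH dehydrogenase ND (27 genes, 0.34, adjusted p = 0.00441) and symbols that start with CO (10 genes, 0.46, adjusted p = 0.0261), all from the authors' deposited table. Centred on the ribosomal protein list, the medians were 0.20 for Nup, 0.11 for mRp and 0.07 for CO, and turned to -0.05 for ND, -0.07 for eI and -0.01 for Rp. In the Pc mutant none of the 38 families was called by cameraPR, and 6 had an unadjusted p under 0.05, in the authors' deposited table. The cuticle protein families Cpr (median -0.57) and Lcp (-0.60), the cytochrome P450 genes Cyp (-0.29) and Osi (-0.79) had the direction down, and Rp (0.07) and Spn (-0.0032, against its direction) had the direction up.

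Genes on chromosome 4, the arm with the most PSC and Su(z)12 peaks per Mb, were called in ph RNA interference more often than others. Of 77 genes 69 were called, 60 of them lower and 9 higher (odds ratio 4.48, 95% interval 2.15 to 10.8, Fisher's exact test, adjusted p = 1.57e-05 over 6 arms). In the Pc mutant 7 of 78 were called (odds ratio 0.899, adjusted p = 1). Strata of mean count or gene length were not run for the arms, and a link with binding was not tested. Over all arms, 66% of tested genes were called in ph RNA interference, and 80.54% of those with a mean count of at least 50. The strongest and the third Su(z)12 peaks lay 19746 and 5036 bp from the first position of their arms. The strongest PSC peak lay 3093 bp from the last annotated gene or listed peak position of its arm. Tested genes within 50 kb of the end of an arm away from the centromere, with chromosome 4 left out, were too few to show a difference. Of these, 4 of 10 were higher in ph RNA interference against 31.19% elsewhere (odds ratio 1.47, interval 0.305 to 6.21, exact p = 0.514). This was 1 of 8 such tests, none of which passed 0.05.

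Standard errors of photoreceptor genes in the authors' deposited table for ph RNA interference had a median ratio of 1.02 to those of 50 genes matched on mean count and fold change, and those of cell cycle genes had 0.819. Whether libraries differed in residual retinal tissue, or counting noise at low levels set these errors, cannot be told apart, since 98.57% of the genes matched to photoreceptor genes were called lower too and can come from the same tissue. No biological explanation was tested.

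Over the 22 lists, the same ratio was highest for heat shock genes (6.64, over 1 for 12 of 12), haemocyte markers (3.1, over 1 for 15 of 15) and fat body markers (2.11, over 1 for 12 of 14).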
